A study of Arabidopsis thaliana with 18 samples.

How the data were processed

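Small RNA libraries of Arabidopsis thaliana Col-0 seeds were analysed for 10 of the 18 samples of the series. Per the labels, flowers were pollinated 24 h after emasculation and seeds were taken 6 days after pollination, from about 20 siliques for each cross and about 50 for the dissected tissues, and RNA of 18 to 30 nt was isolated from a gel. The other 8 samples, laser-dissected tissues in 4 groups, were not analysed here. Groups followed the labels, with 1 library in each of 7 whole-seed crosses and 3 tissues.

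Per the file headers, each file analysed listed 1 line for every exact match of a small RNA, with its strand, its length and a normalised read count, which is a signal and not a whole number of reads. In every file analysed this signal summed to between 9999581 and 10000397, and, as the values show, the authors had divided each sequence's reads equally over its matches. CASAVA 1.8 and the genome build TAIR10 were named in the submitters' processing notes. Bowtie 1.0 was named there for samples not analysed here, and the aligner of the files analysed was not given in the sources used here. The wild type × wild type and tissue files held reads of 18 to 30 nt and the other 6 held 18 to 28 nt.

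Reads were recovered from the signal. In each file the value of a sequence times its number of matches was a multiple of 1 step, between 0.505 and 3.48 in the deposited unit, and the multiple was taken as the number of reads. It was whole within 0.05 plus the rounding of the deposited values for 99.78% to 99.96% of sequences with 1 match and for 98.5% to 99.8% of those with 2 to 100 matches. Over all libraries there were 7237896 distinct sequences. The planned design assumed read counts, and the exact intervals were computed on these recovered reads. No tool that models the spread between replicates was run, because no group had any.

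Annotation came from TAIR10.1 (RefSeq), whose nuclear chromosomes and chloroplast have the lengths the files show. The mitochondrion differs, so no mitochondrial coordinate was used. Reads on annotated rRNA, tRNA, snRNA or snoRNA in the same strand, and sequences that also match the chloroplast or mitochondrion, were left out. This kept 83.4% (embryo) to 99.5% (wild type × nrpd1a) of recovered reads, which are the denominator of reads scaled to per-million kept reads (RPM). Reads from the 45S ribosomal RNA block, from 2000 bp upstream to 8000 bp downstream of each annotated nuclear 18S rRNA start, were kept in the main values, since they did not lie on annotated rRNA in the same strand, and were left out in an alternative chosen after seeing the data. They took up to 65.3% of kept reads, and a large block of this kind lowers every other value in RPM. Reads with 1 match were 26.4% of 24-nt reads in rdr2 × rdr2 and 87.4% in wild type × rdr2. A transposable element annotation was not used here, and the 4843 annotated pseudogenes stand in its place.

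Windows of 500 bp needed at least 20 uniquely matched 24-nt reads. A window was lower in a homozygous mutant when its ratio was 0.25 or less with the 95% interval below 0.5. Reciprocal crosses were compared at the windows lower in the homozygous mutant, with a window called at 2-fold and an interval that excludes 1. A window was dominant in a tissue at 4-fold over both others with intervals beyond 2-fold. Ratios have exact conditional binomial intervals and shares Clopper-Pearson intervals, log2 ratios of windows used a pseudocount of 0.5 reads, and a count of 0 was set to a floor of 3 reads. Intervals of medians over lost windows came from the ranks of the windows, and those of the strongest windows from resampling these windows. Both treat windows as independent and do not measure the spread between libraries. Pericentromeric sequence was taken as 2 Mb on each side of the 1-Mb stretch of a chromosome with fewest protein-coding genes. Reads near the 27444 protein-coding genes were counted in the body plus 1 kb, so that neighbouring genes share reads.

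The genes named follow a rule: every measured list member (at least 20 reads in the libraries compared), the 10 genes with the largest rise and the 10 with the largest fall by the interval bound nearest to 1 among those with at least 100 reads in either library, the 5 such windows each way, and the miRNA families at least 2-fold apart with an interval beyond 1.5. The text gives examples of these. The lists held 12 maternally expressed and 10 paternally expressed imprinted genes, 19 type I MADS-box genes, 4 genes with siRNA-targeted promoters, 8 TAS loci and markers of embryo (8 genes), endosperm (6), seed coat (16) and leaf or silique (4). AGL36 and PHE1 stand on an imprinted list and the MADS-box list, FWA, SDC and ALN on the maternally expressed and promoter lists, and MEA and FIS2 on the maternally expressed and endosperm lists. List medians were placed among 10000 random lists of the same size matched on level in 10 bins. Of 51 mature miRNA sequences 50 matched an annotated miRNA gene and formed 38 families. The groups, lists, thresholds, tests and most alternatives were fixed before the data were examined.

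The alternatives fixed in advance were scaling to reads of the listed miRNAs, reads shared over all matches, at least 50 reads per window, 1000-bp windows, sequences read once left out, 23- and 24-nt reads together, other denominators and distinct sequences for the size classes, gene body only or plus 2 kb, TAS reads of 20 to 22 nt, miRNA reads by their first 18 nt, and marker reads of 25 to 30 nt. Chosen after seeing the data were the omission of the 45S block, scaling to unique 24-nt reads, reads of 18 to 28 nt only, all annotated mature sequences and the other reference libraries.

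Each step was tested on simulated reads drawn at the real depths. Of 200 windows lowered 8-fold, 191 were called for nrpd1a × nrpd1a and 193 for rdr2 × rdr2, and all 200 at 50-fold, with 0 calls among 7647 unchanged windows. In the reciprocal crosses 98 (nrpd1a) and 100 (rdr2) of 200 windows changed 2-fold were called, and 200 and 199 at 4-fold, with 7 to 18 calls among 7647 unchanged windows. Of 200 tissue windows raised 8-fold 196 were called. Of 200 genes changed 4-fold, 176 were called for nrpd1a × nrpd1a among 5182 and 188 for nrpd1a × wild type against wild type × nrpd1a among 6855, with 91 calls among unchanged genes in each. Families raised 4-fold were all called. Simulated intervals held the true ratio in at least 95.7% of cases. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.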

Results

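Small RNAs of 18 to 30 nt were sequenced from developing seeds of Arabidopsis thaliana accession Col-0, collected 6 days after pollination. The 7 whole-seed libraries came from wild type × wild type, nrpd1a × nrpd1a, rdr2 × rdr2 and the reciprocal crosses of each mutant with the wild type. The parent named first was taken as the mother, the usual convention. Another 3 libraries came from dissected embryo, endosperm and seed coat. NRPD1 encodes the largest subunit of RNA polymerase IV, and RDR2 encodes the RNA-dependent RNA polymerase that copies its transcripts into the double-stranded precursors of 24-nt siRNAs. The series addresses which parent's NRPD1 and RDR2 the siRNAs of the seed depend on, and in which seed tissue the siRNAs lie. Between 2859202 reads (endosperm) and 19726666 reads (wild type × rdr2) were recovered per library from the deposited values, and between 2812828 and 19587090 were kept after reads of structural RNAs and organelles were left out. Uniquely matched 24-nt reads numbered from 182013 in nrpd1a × nrpd1a to 8006634 in wild type × rdr2. Each group held 1 library, so no difference has a replicate check. Every comparison is of those libraries, not of the conditions, and the exact 95% intervals cover counting error only.

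Reads in the sense direction on exons of the 2 mutated genes were few in every library. NRPD1 (AT1G63020, chromosome 1, 23354685 to 23362589, minus strand) had 6 reads in wild type × wild type, 46 in nrpd1a × nrpd1a, 43 in nrpd1a × wild type and 6 in wild type × nrpd1a. It had 52 in rdr2 × rdr2, 34 in rdr2 × wild type and 13 in wild type × rdr2. RDR2 (AT4G11130, chromosome 4, 6780449 to 6784632, plus strand) had 3 reads in wild type × wild type, 16 in rdr2 × rdr2, 30 in rdr2 × wild type and 15 in wild type × rdr2. It had 19.5 in nrpd1a × nrpd1a, 15 in nrpd1a × wild type and 5 in wild type × nrpd1a. In embryo, endosperm and seed coat NRPD1 had 3, 1 and 7 reads and RDR2 had 13, 2 and 5. Short fragments of an mRNA do not measure its level and do not show which part of the gene a mutation removes, so these reads do not check the labels.

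Reads of 24 nt, the length of most RNA polymerase IV siRNAs, made up 50.9% of kept reads in wild type × wild type (95% Clopper-Pearson interval 50.9 to 51.0), 5.13% in nrpd1a × nrpd1a (5.12 to 5.14) and 5.29% in rdr2 × rdr2 (5.28 to 5.30). The share was 9.93-fold lower in nrpd1a × nrpd1a and 9.63-fold lower in rdr2 × rdr2 than in wild type × wild type. Reads of 21 nt took a larger share in both, by 2.21-fold and 2.20-fold. The reciprocal crosses lay apart. With the mutant mother 24-nt reads were 11.9% (nrpd1a) and 11.0% (rdr2), and with the mutant father 41.6% and 46.7%. The share with the mutant mother was thus 3.50-fold lower for nrpd1a and 4.24-fold lower for rdr2. In the dissected tissues 24-nt reads were 27.0% in embryo, 54.1% in endosperm and 32.02% in seed coat. Reads from the 45S ribosomal RNA gene block were 65.3% of kept reads in embryo, 47.4% in seed coat and 6.24% in endosperm, and from 5.52% in wild type × wild type to 32.3% in nrpd1a × nrpd1a among whole seeds. Without that block the 24-nt shares were 61.1% in embryo, 57.1% in endosperm and 52.9% in seed coat, so that embryo over seed coat went from 0.844 to 1.15, and the falls in nrpd1a × nrpd1a and rdr2 × rdr2 were 23.2-fold and 23.01-fold. Counted as distinct sequences, each taken once, the mutant-mother share over the mutant-father share was 0.976 for nrpd1a and 1.00 for rdr2.

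**Figure D1:**
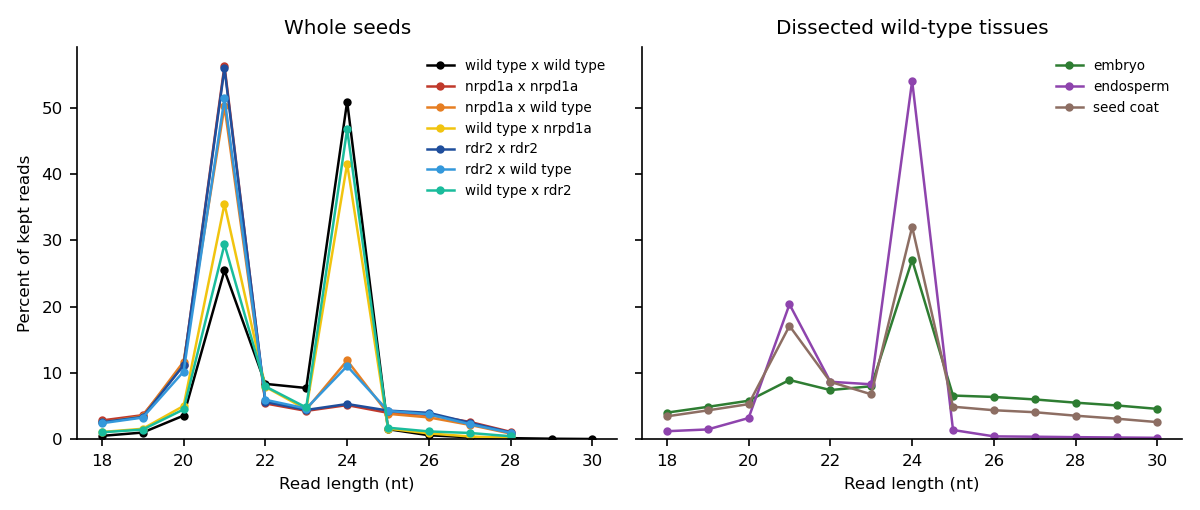
Percent of kept reads (vertical axis) of each length in nt (horizontal axis) in the 7 whole-seed and 3 tissue libraries, 1 library per group. At 24 nt, wild type × wild type stands at 50.9%, nrpd1a × nrpd1a at 5.13% and rdr2 × rdr2 at 5.29%; leaving out the 45S block turns the order of embryo (27.0%) and seed coat (32.02%).

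Loci with 24-nt siRNAs in wild-type seeds lost nearly all of them when both parents were mutant. Of 7847 windows of 500 bp with at least 20 uniquely matched 24-nt reads in wild type × wild type, 7704 (98.2%) were lower in nrpd1a × nrpd1a and 7711 (98.3%) in rdr2 × rdr2. In 5281 and 5301 windows no read was left. Summed over the windows, reads scaled to per-million kept reads (RPM) went from 421884 to 8246 in nrpd1a × nrpd1a, 51.2-fold lower, and to 7922 in rdr2 × rdr2, 53.3-fold lower. The median log2 ratio was −6.50 (quartiles −7.51 and −5.93) and −6.58 (−7.63 and −5.96). Scaled to each library's own uniquely matched 24-nt reads, which takes the loss of their total out, only 966 and 1041 windows were lower. The largest fall in nrpd1a × nrpd1a by its interval was on chromosome 2 (4106501 to 4107000), 145 bp from AT2G10557, with 0 reads against 2637 in wild type × wild type, at least 1190-fold lower against a floor of 3 reads. In rdr2 × rdr2 it was the window at AT3G16930 (chromosome 3, 5778501 to 5779000), with 0 against 5450 reads, at least 2511-fold lower. At AT1G13760 (chromosome 1, 4720001 to 4720500) the window fell 2972-fold in rdr2 × rdr2.

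The 7704 windows lower in nrpd1a × nrpd1a were all lower in rdr2 × rdr2 as well. With nearly every window lower in each comparison, independent sets of these sizes would already share 7570.48. In 20 simulations of unchanged libraries 0 windows were lower in either comparison, so the simulated overlap of 0 was fixed by that, and neither number tests agreement between the mutants. Both comparisons used the same wild type × wild type library, so part of the excess may come from the shared control. Against the wild type × rdr2 library instead, 9070 of 9441 windows were lower in nrpd1a × nrpd1a. Against wild type × nrpd1a, 9288 of 9548 were lower in rdr2 × rdr2. Only 77 and 79 windows were at least 2-fold higher. Among the largest rises in nrpd1a × nrpd1a were a window at an exon of MIR8121 (chromosome 2, 16588001 to 16588500; 31.9-fold, 95% interval 25.3 to 40.9), 1 at MIR158a (34.0-fold) and 1 at the non-coding gene AT3G06365 (chromosome 3, 14201001 to 14201500; 23.5-fold). In rdr2 × rdr2 the MIR158a window was 39.9-fold and the AT3G06365 window 22.2-fold higher.

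Near protein-coding genes (gene body plus 1 kb on each side) the same loss was seen. In nrpd1a × nrpd1a, 24-nt reads near GPT fell 1124-fold (18 against 14941 reads), near HGL1 759-fold, near AT3G04490 700-fold and near PYL10, an abscisic acid receptor gene, 686-fold. In rdr2 × rdr2 they fell 2881-fold near AT1G13755, 2155-fold near AT1G13760, 1749-fold near AT5G56075 and 1595-fold near HGL1, and CTL2 had 0 reads against 6064. Of the genes with the largest rises, CYT1, which encodes a mannose-1-phosphate guanylyltransferase and lies beside MIR8121, was 32-fold higher in nrpd1a × nrpd1a and 24.0-fold higher in rdr2 × rdr2. ASD1 (32.2-fold and 37.8-fold), the lipid transfer protein gene LTP6 (26.8-fold and 34.7-fold), SHD (27.7-fold and 40.9-fold) and NOP56 (13.8-fold and 16.2-fold) were higher in both. The median over all measured genes was −4.90 in nrpd1a × nrpd1a and −4.86 in rdr2 × rdr2 on the log2 scale. Scaling to miRNA reads shifted every gene by a further −2.12 and −2.07, leaving out the 45S block by 0.48 in both, and scaling to unique 24-nt reads by 4.99 in both.

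Of the 18 genes on the 4 lists that were measured in nrpd1a × nrpd1a, 16 fell, 1 rose and 1 did neither, and in rdr2 × rdr2 17 of 20 fell and 1 rose. All 7 measured maternally expressed imprinted genes fell in nrpd1a × nrpd1a, with a median log2 ratio of −3.45 at percentile 93.6 among random lists matched on level. They included AGL36 (208-fold), the homeodomain gene FWA, silenced by DNA methylation in vegetative tissue (11.0-fold), and HDG9 (11.5-fold). In rdr2 × rdr2 7 of 8 fell, with a median of −3.98 at percentile 80.4, and HDG8 had a ratio of 0.434 and did not pass. Of the paternally expressed genes 3 of 4 fell in each, with medians of −5.29 and −6.30 at percentiles 70.6 and 33.9. YUC10 (chromosome 1, 18091681 to 18093878), an auxin biosynthesis gene, fell 578-fold in nrpd1a × nrpd1a and 794-fold in rdr2 × rdr2 (29 against 16657 reads). HDG3, at 1.81 and 1.93 times the wild-type level, did neither. Of the type I MADS-box genes 7 of 8 fell in nrpd1a × nrpd1a and 8 of 9 in rdr2 × rdr2, with medians of −7.44 and −6.35 at percentiles 23.6 and 49.8. AGL91 (chromosome 3, 2091262 to 2091798) fell 624-fold and 1369-fold, AGL40 433-fold and 774-fold, and AGL62, needed for the syncytial phase of the endosperm, 377-fold in nrpd1a × nrpd1a. AGL87 (chromosome 1, 7981722 to 7984334) was 3.21-fold higher (2.60 to 4.00) and 3.47-fold higher, but lower when scaled to miRNA reads (0.737 and 0.824). All 3 measured genes with siRNA-targeted promoters fell in both, with medians of −3.13 and −3.81 at percentiles 86.2 and 72.1. SDC, an F-box gene silenced by RNA-directed DNA methylation, fell 7.74-fold and 13.8-fold, and ALN, which encodes allantoinase, 9.48-fold and 16.1-fold. Fragments of embryo (4.85-fold and 5.69-fold), seed coat (4.65-fold and 5.60-fold) and leaf and silique (4.47-fold and 4.93-fold) marker mRNAs were all higher in RPM in these libraries than in wild type × wild type, between 1.02 and 1.35 for these 3 kinds when scaled to miRNA reads. Endosperm markers, most of whose reads lay at AGL62, itself a 24-nt locus, were at 0.0996 and 0.119.

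When only 1 parent was mutant, windows that needed the gene kept fewer siRNAs in RPM with the mutant as mother than as father. Among the 7704 windows lower in nrpd1a × nrpd1a, 4337 (56.3%) were at least 2-fold lower in nrpd1a × wild type than in wild type × nrpd1a, 1249 (16.2%) were at least 2-fold higher and 2118 were neither. For rdr2, 4387 of 7711 (56.9%) were lower with the mutant mother, 1098 (14.2%) higher and 2226 neither. The median log2 ratio of mother over father was −1.44 (95% interval −1.50 to −1.38, quartiles −3.09 and 0.25) for nrpd1a and −1.53 (−1.59 to −1.47, quartiles −3.30 and 0.10) for rdr2. These 2 intervals treat windows of 1 library pair as independent, so they are not intervals of the cross effect. Summed RPM was 24122 against 341557 for nrpd1a, 14.2-fold lower with the mutant mother, and 19524 against 389553 for rdr2, 20.0-fold lower. Against wild type × wild type the median was −2.24 with the nrpd1a mother and −0.72 with the nrpd1a father, and −2.51 and −0.84 for rdr2, which became −4.19 and −1.78, and −4.48 and −1.53, when scaled to miRNA reads. Under that scaling the medians of mother over father were −2.34 and −2.81, with 70.2% of windows lower and 4.30% higher with the nrpd1a mother and 76.0% and 0.969% with the rdr2 mother. The 45S block took 29.6% of kept reads with the nrpd1a mother against 9.69% with the nrpd1a father, and 31.1% against 10.2% for rdr2, and without it the medians were −1.09 and −1.14. Scaled to each library's own unique 24-nt reads, so that a change in their total is taken out, the medians of the same windows turned to 1.02 and 1.34, with 1449 windows lower and 3617 higher with the nrpd1a mother and 1346 and 3859 with the rdr2 mother. Among the windows lower in the homozygous mutant under that scaling the medians were −3.23 and −3.71. With at least 50 reads per window the medians were −2.64 and −2.78, and without sequences read once −2.84 and −2.97.

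**Figure D2:**
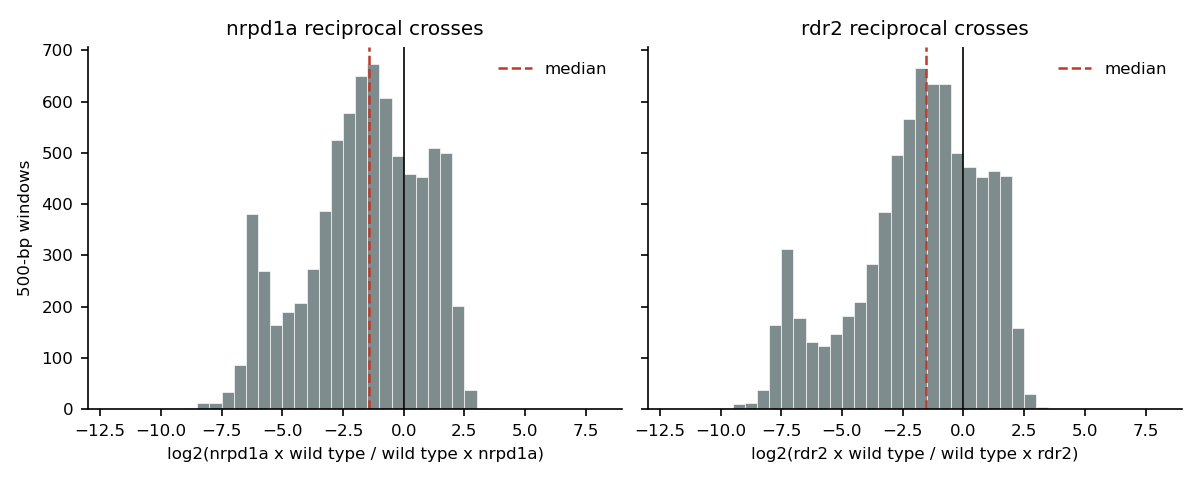
Number of windows (vertical axis) by log2 ratio of 24-nt RPM, mutant mother over mutant father (horizontal axis), for nrpd1a and rdr2, 1 library per cross. The medians lie at −1.44 and −1.53, at −2.34 and −2.81 when scaled to miRNA reads, and at 1.02 and 1.34 when scaled to unique 24-nt reads.

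Among the windows with the largest falls with the nrpd1a mother were those at AT5G26320 (1 against 958 reads, ratio 0.00156, 95% interval 3.94e-05 to 0.00869), AGL33 (193-fold), AT5G04865 (186-fold) and DWF4, a brassinosteroid biosynthesis gene (118-fold), and 1 that lay 23 bp from AT5G53610 (2 against 1044 reads, ratio 0.00286, 0.000345 to 0.0103). With the rdr2 mother the largest by its interval lay on chromosome 2 (2865001 to 2865500), 1567 bp from the pseudogene AT2G06950, with 3 against 2540 reads, a ratio of 0.00170 (0.000350 to 0.00497). The next lay 679 bp from AT5G56070 (273-fold) and at TPS2 (358-fold), AT1G60400 (303-fold) and AT2G24560 (300.4-fold). Among the windows with the largest rises with the mutant mother were those at the pseudogenes AT5G28523 (10.1-fold) and AT3G26260 (8.50-fold) for nrpd1a, and for rdr2 those 284 bp from AT4G04409 (67 against 2 reads, ratio 48.1, 95% interval 12.8 to 406), at AT3G43433 (7.95-fold) and 218 bp from AT3G30219 (9.20-fold). Across windows the ratios of the nrpd1a and rdr2 crosses, which share no library, had a Pearson correlation of 0.934 and a Spearman correlation of 0.934; windows are not independent replicates. The direction was the same in 92.4% of windows. In both crosses 3944 windows were lower with the mutant mother and 952 were higher, and 0 had opposite calls, against 2 when scaled to miRNA reads.

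Near genes, 24-nt reads were 86.6-fold lower with the nrpd1a mother at YUC10 (185 against 23891 reads; ratio 0.0115, 95% interval 0.00994 to 0.0133) and 143-fold lower with the rdr2 mother. Reads also fell near AT4G26460 (93.1-fold), AT1G33080 (92.0-fold), AT1G13470 (85.2-fold) and PERK7 (77.4-fold) for nrpd1a, and near AT1G13460 (230-fold), RUS3 (224-fold), TPS2 (213-fold) and BSK11 (201-fold) for rdr2. The largest rise with the mutant mother was near AT2G23834, 410-fold for nrpd1a (12386 against 45 reads) and 194-fold for rdr2. AT1G78480 (159-fold and 121-fold), the histone H2A gene HTA4 (129-fold and 101-fold), AT1G65735 (48.5-fold and 33.9-fold) and cICDH, an isocitrate dehydrogenase gene (22.2-fold and 22.0-fold), were higher in both crosses. SUVH2, a gene of RNA-directed DNA methylation (46.9-fold), and the DNA repair gene BRCA1 (37.6-fold) were among the 10 largest for nrpd1a. The median over all measured genes was −0.59 in both crosses, and scaling to miRNA reads shifted every gene by −0.91 for nrpd1a and −1.29 for rdr2, leaving out the 45S block by 0.36 and 0.38, and scaling to unique 24-nt reads by 2.47 and 2.87.

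Among listed genes, 10 of 26 fell, 4 rose and 12 did neither with the nrpd1a mother, and 14 of 27 fell, 4 rose and 9 did neither with the rdr2 mother. Scaled to miRNA reads the split of lower and higher was 18 and 1 for nrpd1a and 22 and 0 for rdr2, and without the 45S block 10 and 6 for nrpd1a and 9 and 4 for rdr2. Of the type I MADS-box genes 6 of 12 fell and 1 rose for nrpd1a (median −1.21, percentile 51.4), and 8 of 13 fell and 1 rose for rdr2 (median −1.40, percentile 34.0). AGL62 fell 79.0-fold and 160-fold, AGL91 73.4-fold and 161-fold, and AGL40 68.3-fold and 166-fold, while AGL28 was 3.55-fold and 4.50-fold higher. Of the 5 measured paternally expressed genes 3 fell and 2 rose in each (medians −1.79 and −2.36, percentiles 21.2 and 12.4). SUVH7 fell 8.72-fold and 14.9-fold, and TAR1, an auxin biosynthesis gene, 3.49-fold and 5.24-fold. HDG3 was 4.20-fold and 2.12-fold higher and PKR2 3.23-fold and 2.28-fold higher. For rdr2 both went below 1 when scaled to miRNA reads (0.866 and 0.934), and with matches shared PKR2 was at 0.435 and 0.309. Of the maternally expressed genes 1 of 9 fell and 1 rose for nrpd1a (median −0.57, percentile 64.0), and 4 of 9 fell and 1 rose for rdr2 (median −0.61, percentile 64.2). FWA fell 3.93-fold and 2.09-fold, AGL36 had a ratio of 0.579 for nrpd1a and fell 3.22-fold for rdr2, and the Polycomb gene FIS2 was 3.44-fold and 2.11-fold higher, the last at 0.862 when scaled to miRNA reads. Of the 4 genes with siRNA-targeted promoters 1 fell for nrpd1a (median −0.82, percentile 36.8) and 2 for rdr2 (median −0.49, percentile 52.4), with SDC at 1.62 and not past the rule for nrpd1a. Seed coat marker fragments were 4.79-fold higher with the nrpd1a mother and 2.66-fold higher with the rdr2 mother (2.55 and 1.09 when scaled to miRNA reads), and leaf and silique marker fragments 5.25-fold and 2.03-fold higher (2.80 and 0.830). Embryo marker fragments were at 1.14 (0.509 to 2.49) and 0.312 (0.0928 to 0.840), and endosperm marker fragments at 0.147 and 0.0766.

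The strongest siRNA loci lost nearly all their reads with a mutant mother and far fewer with a mutant father. The 100 windows with most 24-nt reads in wild type × wild type held 54.6% of its uniquely matched 24-nt reads, 52.6% in wild type × nrpd1a and 52.4% in wild type × rdr2, but 4.11% in nrpd1a × wild type and 2.34% in rdr2 × wild type. In RPM they stood at 0.783 and 0.884 of the wild type × wild type level with the nrpd1a and rdr2 fathers, but at 0.375 and 0.547 when scaled to miRNA reads, against 0.0110 and 0.00543 in RPM with the mothers (0.00282 and 0.00137). Among tissues they held 51.2% in seed coat, 30.3% in endosperm and 4.00% in embryo. In RPM the same windows gave 126325 in seed coat, 131516 in endosperm and 6227 in embryo. Endosperm over seed coat was thus 1.04, but 0.584 without the 45S block and 0.994 when scaled to miRNA reads, while embryo stayed below seed coat under both (0.0746 and 0.138). The strongest window (chromosome 4, 13902501 to 13903000), 501 bp from PYL10, had 8706 RPM in wild type × wild type, 6134 with the nrpd1a father and 82.4 with the nrpd1a mother, and 6556 with the rdr2 father and 47.5 with the rdr2 mother. In seed coat, endosperm and embryo it had 3336, 2489 and 140. The next windows lay at the long non-coding RNA gene AT3G08370 (chromosome 3, 20031001 to 20031500; 6812 RPM in wild type × wild type) and 444 bp from AT3G50030 (chromosome 3, 18545501 to 18546000; 6548).

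**Figure D3:**
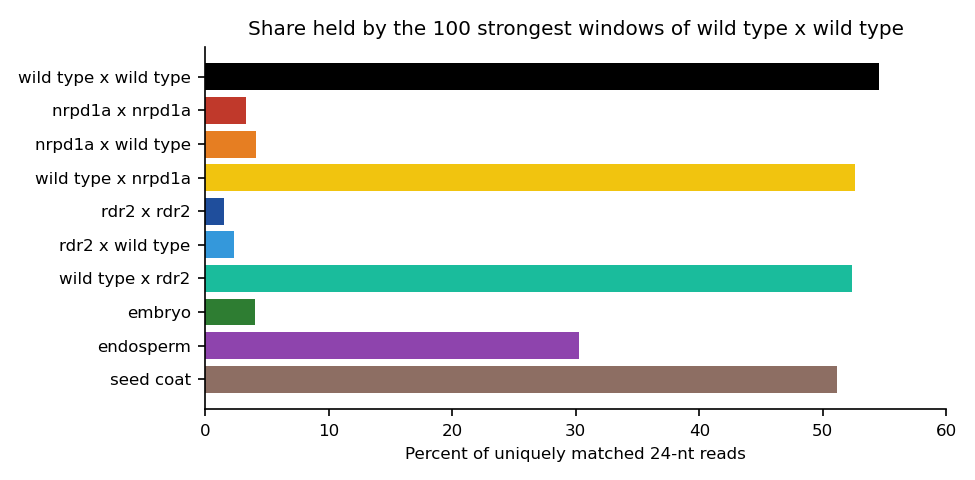
Percent of uniquely matched 24-nt reads (horizontal axis) that lay in the 100 windows strongest in wild type × wild type, 1 bar per library. Shares are 51.2% to 54.6% in wild type × wild type, both crosses with a mutant father and seed coat, 30.3% in endosperm and at most 4.11% in the other 5 libraries.

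Of the 15738 windows with at least 20 uniquely matched 24-nt reads in the 3 tissues together, few stood out in 1 tissue in RPM, with 550 dominant in endosperm, 55 in embryo and 23 in seed coat. The order of embryo and endosperm depended on the scaling. Scaled to miRNA reads, 3208 windows were dominant in embryo, 105 in endosperm and 5 in seed coat, and without the 45S block 2597, 64 and 28. Endosperm was above seed coat with a median log2 ratio of 2.44 and 11285 windows at least 2-fold higher against 90 lower. Without the 45S block the median was 1.61, with 7656 higher and 446 lower, and per unique 24-nt reads 1.63, with 7673 and 433. Embryo was above seed coat with a median of 2.22 and 9188 windows higher against 1965 lower, which became 3.71 with 11956 and 939 when scaled to miRNA reads and 2.81 with 10639 and 1427 without the 45S block. Embryo against endosperm had a median of −0.50 with 1246 windows higher and 5021 lower, which turned to 1.06 with 7385 and 1402 when scaled to miRNA reads and to 0.93 with 6839 and 1539 without the 45S block. Across windows the log levels of endosperm and seed coat had a Pearson correlation of 0.678, those of embryo and endosperm 0.391 and those of embryo and seed coat 0.0821. Windows with no read in seed coat included 1 at the circadian clock gene CCA1 (132 reads in endosperm) and 1 at the pseudogene AT5G28940 (119 reads in embryo). The largest fall of embryo below seed coat was at AT1G08795 (49.2-fold), that of endosperm below seed coat at AT3G06365 (26.1-fold) and that of embryo below endosperm 839 bp from AT4G10655 (209-fold). The 45S block was likewise lower in endosperm (6.24% of kept reads) than in seed coat (47.4%), and whether the reads at AT3G06365 belong to it was not tested.

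Embryo was below seed coat near TOC33, a chloroplast import receptor gene (42.2-fold), AGL62 (26.2-fold), PYL10 (23.9-fold), AGL40 (21-fold), AGL91 (19.6-fold) and YUC10 (14.7-fold), and above it near AT2G07190 (38.0-fold), AT2G05642 (34.5-fold) and AT2G07240 (21.8-fold). FWA had 3 reads in embryo and 28 in seed coat, a ratio of 0.115 (0.0224 to 0.372). Of the 15 listed genes measured, 6 fell and 6 rose in embryo against seed coat. The 8 measured type I MADS-box genes were 4 lower and 4 higher, with a median of −1.11 at percentile 28.6 that the miRNA scaling, a shift of 1.49 for every gene, turned positive. Of 6 maternally expressed genes 1 was lower and 3 higher (median 0.81, percentile 79.2), among them AGL36 (5.10-fold higher), and of 2 paternally expressed genes YUC10 was lower. Leaving out the 45S block shifted embryo over seed coat by 0.60, and the median over all genes was 0.10. Of 3 genes with siRNA-targeted promoters SDC was 2.04-fold higher and FWA lower. Leaf and silique marker fragments were 8.90-fold higher in embryo than in seed coat.

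Endosperm was above seed coat near all 10 measured type I MADS-box genes, with a median of 2.65 at percentile 98.9, among them AGL87 (13.5-fold), AGL90 (15.4-fold), AGL62 (3.08-fold) and AGL91 (2.81-fold). AGL62, AGL91, AGL40 and AGL23 stayed above seed coat without the 45S block, but by less than 2-fold. All genes together had a median of 1.27, and leaving out the 45S block shifted endosperm over seed coat by −0.83. Of the 18 listed genes measured 15 were higher and 0 lower, against 8 higher and 1 lower without the 45S block. Of 7 maternally expressed genes 5 were higher (median 1.503, percentile 68.6), with AGL36 4.83-fold higher and FWA at 0.947. YUC10 was 3.09-fold higher, 1 of 2 paternally expressed genes measured. Of 3 genes with siRNA-targeted promoters, SDC (4.19-fold) and ALN (2.88-fold) were higher. CCA1 had 242 reads in endosperm and 0 in seed coat, and PSI-P was 68.4-fold and UNE4 33.2-fold higher. GILT was 27.4-fold lower, and DELTA-VPE, a vacuolar processing enzyme gene of the seed coat, had 1 read against 138, a ratio of 0.0101 (95% interval 0.000254 to 0.0573). LIG6 was 2.11-fold lower but 4.47-fold higher with reads in the gene body only.

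Embryo was below endosperm near AT2G25010 (208-fold), AT1G28630 (81.2-fold), AGL62 (80.6-fold), the ethylene response factor gene ERF11 (73.9-fold), AGL40 (55.1-fold), AGL91 (55.0-fold) and YUC10 (45.5-fold), and above it near RR3, a cytokinin response regulator gene (6.44-fold), AT4G21660 (5.06-fold) and AT1G15410 (4.90-fold). The median over all genes was −1.15, shifted by 1.56 with the miRNA scaling and by 1.43 without the 45S block. Of the 17 listed genes measured 13 were lower and 0 higher, against 7 lower and 1 higher under each of these. The type I MADS-box genes were lower in 9 of 10, with a median of −3.04 at percentile 0.72. Of 6 maternally expressed genes 2 were lower (median −0.86, percentile 77.0, positive under both other scalings), both measured paternally expressed genes were lower (median −3.42, percentile 10.1), and 2 of 3 genes with siRNA-targeted promoters were lower. TAR1, SDC, AGL34 and AGL90, at 0.390, 0.488, 0.392 and 0.396, were above 1 under both other scalings.

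Windows dominant in embryo and those dominant in seed coat in RPM lay on opposite sides in the reciprocal crosses. For nrpd1a, mother over father had a median log2 of 1.40 in 6 embryo windows (percentile 98.9 among random window sets matched on wild-type level), −1.68 in 239 endosperm windows (percentile 4.21) and −3.53 in 8 seed coat windows (percentile 7.52). For rdr2 the medians were 1.97 (percentile 100), −1.97 (percentile 0.08) and −4.30 (percentile 3.33). Without the 45S block more windows fell in the embryo class, and the medians were 2.01 for nrpd1a in 624 embryo windows and 2.01 for rdr2 in 623, against −3.94 and −4.49 in 14 seed coat windows. Scaled to miRNA reads only 2 seed coat windows were left, too few for a median. The embryo medians were then 0.70 and 0.27, with 39 windows lower with the nrpd1a mother against 208 with the father, but 79 against 51 for rdr2. Across the 7847 windows, log levels in nrpd1a × wild type and rdr2 × wild type had correlations of 0.742 and 0.729 with embryo and of 0.229 and 0.141 with seed coat. For wild type × nrpd1a and wild type × rdr2 the correlations were 0.844 and 0.822 with seed coat, and 0.264 and 0.295 with embryo. With endosperm they were 0.743 and 0.755 for these 2 crosses, and 0.488 and 0.417 for nrpd1a × wild type and rdr2 × wild type.

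Pericentromeric sequence, 20.98% of the genome, held 69.3% of 24-nt reads in embryo, 48.5% in endosperm and 36.6% in seed coat. In whole seeds it held 54.3% in nrpd1a × wild type and 54.6% in rdr2 × wild type, against 33.3% in wild type × nrpd1a, 33.6% in wild type × rdr2 and 32.5% in wild type × wild type. In nrpd1a × nrpd1a and rdr2 × rdr2 it was 42.1% and 41.9%, but 18.9% and 16.8% of reads with 1 match. Annotated pseudogenes, 8.78% of the genome, held 26.1% in embryo, 20.9% in nrpd1a × wild type, 20.4% in rdr2 × wild type, 16.2% in endosperm and 7.90% in seed coat. They held 9.40% in wild type × wild type, 2.00% in nrpd1a × nrpd1a and 1.91% in rdr2 × rdr2. Other annotated genes, 1.31% of the genome, held 58.5% and 58.4% in nrpd1a × nrpd1a and rdr2 × rdr2. They held 8.16% in wild type × wild type. The ribosomal RNA gene block was kept in all these shares. In nrpd1a × nrpd1a 24-nt reads were 5.13% of 13072477 kept reads with the block and 2.29% of 8853136 without it. In rdr2 × rdr2 they were 5.29% of 13344084 and 2.31% of 9067706. Most 24-nt reads left in these 2 libraries thus lay in the block, and the shares without it were not tested. Protein-coding gene bodies held 19.5% and the 1 kb upstream of genes 13.3% in wild type × wild type, where they are 54.0% and 13.3% of the genome.

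**Figure D4:**
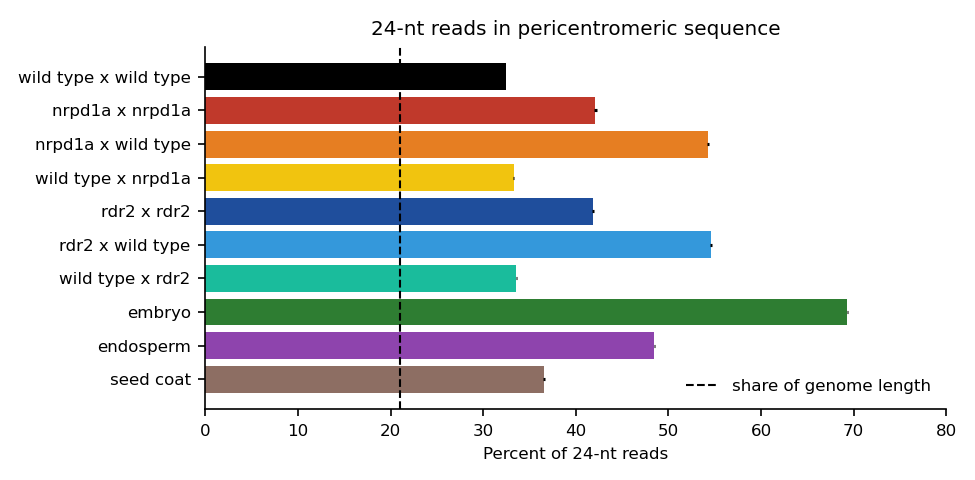
Percent of 24-nt reads, each shared over its matches, in pericentromeric sequence (horizontal axis) in each library, with exact 95% intervals for counting error and a dashed line at the 20.98% this sequence makes of the genome. Embryo (69.3%) and both crosses with a mutant mother (54.3% and 54.6%) lie highest. Among reads with 1 match the homozygous mutants fall below the dashed line (18.9% and 16.8%). Reads of the ribosomal RNA gene block were kept.

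Trans-acting siRNAs, which need RDR6 and not RNA polymerase IV or RDR2, served as a background. Reads of 21 nt at the 8 TAS loci were 1225 RPM in wild type × wild type and 3680 in nrpd1a × nrpd1a, 3.00-fold higher (2.94 to 3.07), and 3.09-fold higher in rdr2 × rdr2, but at 0.689 and 0.734 when scaled to miRNA reads. They were 3.197-fold higher with the nrpd1a mother than with the nrpd1a father (1.71 when scaled to miRNA reads) and 2.18-fold higher with the rdr2 mother (0.891). TAS3 was 7.48-fold and TAS1A 1.26-fold higher in nrpd1a × nrpd1a. Embryo was 3.61-fold and endosperm 4.12-fold above seed coat, with TAS1A 12.7-fold and 10.1-fold higher. Embryo over endosperm was 0.876, but 2.58 when scaled to miRNA reads and 2.36 without the 45S block.

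In RPM most miRNA families were higher in the homozygous mutants than in wild type × wild type. Most were also higher with a mutant mother than with a mutant father. Both held for fewer families when scaled to miRNA reads. A loss of 24-nt reads by itself raises every other value in RPM, since all share the denominator. In nrpd1a × nrpd1a 26 of 30 measured families were higher and 1 lower, and in rdr2 × rdr2 27 of 31 were higher and 1 lower. Scaled to miRNA reads these became 9 higher and 5 lower, and 10 higher and 4 lower. That scaling divides each family by the sum of the listed families, so a rise shared by all of them vanishes by construction. miR167, at 283513 RPM in nrpd1a × nrpd1a and 284126 in rdr2 × rdr2 against 35225 in wild type × wild type, weighs heavily in that sum. The crosses with a mutant father, whose 24-nt shares stayed high, also had more miR167 (152609 in wild type × nrpd1a and 115038 in wild type × rdr2). They lay above wild type × wild type for miR164 (276 and 220 against 48.0) and miR396 (35.9 and 47.9 against 8.70), but below it for miR166 and miR168. Rises over wild type × wild type thus did not follow the 24-nt loss alone. miR396 (23.8-fold), miR390, which triggers TAS3 siRNAs (21.04-fold), miR164 (17.2-fold) and miR172 (10.3-fold) were among the families higher in nrpd1a × nrpd1a under both scalings, while miR156 (2.67-fold) was below 1 when scaled to miRNA reads (0.611). miR163 was 3.64-fold lower in nrpd1a × nrpd1a and 3.78-fold lower in rdr2 × rdr2, and lower under each scaling. This fall depends on the reference library. Wild type × wild type had 17.0 RPM of miR163, but wild type × nrpd1a had 0.212 and wild type × rdr2 0.562. Both lay below nrpd1a × nrpd1a (4.67) and rdr2 × rdr2 (4.50). In the reciprocal crosses 23 of 29 families were higher with the nrpd1a mother and 25 of 30 with the rdr2 mother, against 9 and 7 when scaled to miRNA reads, where 2 were lower with the rdr2 mother. miR395 (20.9-fold and 6.74-fold), miR390 (11.5-fold and 6.33-fold) and miR168, which targets AGO1 (5.77-fold and 9.09-fold), were higher with both mutant mothers.

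Among tissues, embryo had 6 families higher and 14 lower than seed coat of 25 measured, against 9 and 8 when scaled to miRNA reads and 9 and 11 without the 45S block. miR319 (9.25-fold), miR156 (7.89-fold) and miR160 (5.75-fold) were higher in embryo, and miR157 (32.8-fold), miR163 (31.4-fold) and miR164 (11.0-fold) lower. Endosperm had 10 higher and 7 lower than seed coat of 27, against 8 and 9 without the 45S block, with miR845 (39.4-fold), miR395 (18.0-fold) and miR156 (15.8-fold) higher, and miR157 (7.10-fold), miR166 (6.75-fold) and miR165 (5.55-fold) lower. Embryo against endosperm had 3 higher and 15 lower of 28, against 10 and 6 under both other scalings, with miR845 (71.1-fold) and miR396 (36.4-fold) lower and miR160 (4.42-fold) and miR319 (2.99-fold) higher.

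Fragments of marker mRNAs set embryo and seed coat apart, but not endosperm. Embryo markers, the seed storage and oleosin genes and LEC1, had 481 RPM in embryo, 8.18 in endosperm and 2.04 in seed coat. Seed coat markers, genes of flavonoid and mucilage pathways among them, had 551 in seed coat, 60.7 in embryo and 64.4 in endosperm. Endosperm markers had 190 in endosperm, 67.7 in seed coat and 10.4 in embryo, but AGL62, itself a 24-nt locus, held 515 of the 534 reads in endosperm, and among reads of 25 to 30 nt the list had only 6.04 RPM there. SUC5 had 2 reads in endosperm, 34.8 in seed coat and 20 in embryo, EPR1 13, 1 and 2, ZOU 4, 3 and 2, and FIS2 and MEA 0 in all 3. Leaf and silique markers, photosynthesis genes, had 297 in embryo, 8.90-fold above seed coat (33.5), and 7.38 in endosperm. Seed coat markers had 81.8 RPM in wild type × wild type, 110 in wild type × nrpd1a, 129 in wild type × rdr2, 381 in nrpd1a × nrpd1a, 458 in rdr2 × rdr2, 524 in nrpd1a × wild type and 343 in rdr2 × wild type. Embryo markers had 0.725 RPM in wild type × wild type (7 reads) and 0.369 (rdr2 × wild type) to 1.18 (wild type × rdr2) in the reciprocal crosses, below every tissue. They had 3.52 in nrpd1a × nrpd1a and 4.13 in rdr2 × rdr2. For these fragments wild type × wild type was thus not a mixture of the 3 tissue libraries, and the cause was not tested.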

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

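All tests of explanations in this part were chosen only after the results they bear on had been seen.

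Reads left out of the comparisons took a larger share than in wild type × wild type in most libraries. Chloroplast reads were 0.487% of recovered reads in wild type × wild type, against 1.94% in nrpd1a × nrpd1a, 1.89% in nrpd1a × wild type, 1.94% in rdr2 × rdr2, 1.75% in rdr2 × wild type and 0.539% in wild type × rdr2. They were 15.6% in embryo, 1.21% in endosperm and 3.28% in seed coat. Reads with a nuclear match that also match the mitochondrion were 0.124% in nrpd1a × nrpd1a, 0.258% in nrpd1a × wild type, 0.142% in rdr2 × rdr2 and 0.242% in rdr2 × wild type. They were 0.540%, 0.320% and 0.181% in embryo, endosperm and seed coat. Matches placed on the mitochondrion itself were not recovered as reads. They held 0.360% of the deposited signal in wild type × wild type, 0.895% in nrpd1a × nrpd1a and 0.881% in nrpd1a × wild type. They held 0.256% in wild type × nrpd1a, 0.932% in rdr2 × rdr2, 0.958% in rdr2 × wild type and 0.331% in wild type × rdr2. In embryo, endosperm and seed coat they held 1.92%, 0.570% and 1.25%. Reads of rRNA, tRNA, snRNA and snoRNA were 0.0424% in wild type × wild type, 0.208% in nrpd1a × nrpd1a, 0.155% in nrpd1a × wild type and 0.0483% in wild type × nrpd1a. They were 0.201% in rdr2 × rdr2, 0.208% in rdr2 × wild type, 0.0725% in wild type × rdr2, 0.481% in embryo, 0.0903% in endosperm and 0.293% in seed coat. AT1G23200 was the protein-coding gene whose reciprocal calls went opposite ways, with 24-nt reads at 7.45 times the mutant-father level with the nrpd1a mother and 0.319 times with the rdr2 mother, and the difference between the crosses was not tested.

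For the lower 24-nt reads with a mutant mother, one scale factor between the libraries would move all windows alike, but the 100 strongest windows lay a further −4.71 (95% interval −4.75 to −4.68) on the log2 scale from the median of all lost windows for nrpd1a and −5.84 (−5.89 to −5.80) for rdr2. Less seed coat in the mutant-mother libraries would lower seed coat against embryo marker fragments. That ratio was 4.17-fold (2.02 to 8.59) higher for nrpd1a and 8.48-fold (3.23 to 22.3) higher for rdr2, on few embryo marker fragments. It cannot measure seed coat content, since embryo marker fragments in the reciprocal crosses lay below every tissue library in RPM. Leaf and silique marker fragments were also higher in RPM with both mutant mothers. Less seed coat in these libraries thus stays open. Loss of siRNAs made in maternal seed tissue needs the windows with most seed coat over embryo reads to fall most, and the Spearman correlation across windows, which are not independent replicates, was −0.909 for nrpd1a and −0.887 for rdr2. Output in proportion to the 2 maternal and 1 paternal copies in the endosperm allows no median below −1 if the endosperm is the only source. Whole seeds also hold the seed coat, a maternal tissue, and its reads can take the median below that bound. The median of the strongest windows was −6.15 (−6.19 to −6.13) and −7.36 (−7.42 to −7.32), and −3.68 and −4.50 under the scaling that raised it most. These values count only against such output from the endosperm alone. The intervals of these medians, and of the differences from all lost windows, came from resampling the 100 windows and not from replicates. The maternal tissue hypothesis predicts this pattern, but the pattern is not specific to it. The correlation set seed coat against embryo only, so it does not separate seed coat from endosperm as the source. At the strongest windows endosperm stood at 1.04 of seed coat in RPM, and at 0.584 without the ribosomal RNA gene block. More output from maternal than paternal copies in the endosperm, beyond their number, was not tested. Also open as untested are siRNAs deposited earlier by the mother, dosage at weaker windows, and dosage in the endosperm together with seed coat output at the strongest windows.

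Endosperm held many 24-nt reads at the 100 windows strongest in wild type × wild type. The endosperm over seed coat ratio of seed coat marker fragments (0.117) was only 0.112 of that of 24-nt reads at these windows (95% interval 0.0966 to 0.131). This tests seed coat carried over into the endosperm sample only if both libraries recovered fragments alike, which was not shown. Leaf and silique marker fragments were also low in endosperm (0.224), as was the ribosomal RNA gene block (6.24% of kept reads against 47.4%). Embryo marker fragments went the other way (4.01-fold higher, 23 against 8 fragments). Carry-over as the whole source thus stays open. Movement of siRNAs from the seed coat and synthesis at the same loci in the endosperm cannot be told apart, since both give like profiles; the correlation of levels across these windows was 0.860 between endosperm and seed coat and 0.926 between embryo and seed coat.

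miR159 was 83.5 to 830 RPM in whole seeds and 13333 to 46288 in the dissected tissues, and miR167 35225 to 284126 against 469 to 1929. A mixture of the 3 tissues must lie within their range, but miR159 over miR167 in wild type × wild type (0.00237) was 0.000106 of the lowest tissue (22.3), and it was 0.000106 with reads of other 3′ ends included. The labels name no preparation batch, and a batch that follows the longest read length would put wild type × wild type (30 nt) with the tissues, not with the other crosses (28 nt), but of the 19 families outside the tissue range in those 6 crosses 16 lay outside it on the same side in wild type × wild type (84.2%, exact interval 60.4 to 96.6). Handling that differed between whole seeds and dissected tissues stays open, as 16 of 37 families lay outside the tissue range in every whole-seed library; effects of dissection and of any difference in preparation cannot be told apart, since no tissue library was made without dissection. No biological explanation was tested.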

How the results depend on the processing

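The results with a value under another setting were 159 times within their error or within 1.5 times the count, 169 times moved and 11 times reversed for the values that answer a comparison, and 1619, 899 and 44 times for single genes, families and parts. With so many reads the counting intervals are narrow, so small moves pass them. The omission of the 45S block, scaling to unique 24-nt reads, reads of 18 to 28 nt, all annotated mature sequences and the other reference libraries were chosen after seeing the data. The loss of 24-nt reads at windows in both homozygous mutants, and the negative median of mutant mother over mutant father, kept their direction under the miRNA scaling, the omission of the 45S block, matches shared, 50 reads per window, 1000-bp windows, sequences read once left out and 23-nt reads added. Scaling to unique 24-nt reads, which takes out a change in their total, turned the medians at the same windows. No paired analysis was possible because each group analysed held 1 library. Depth was lowest in the dissected tissues, with 2812828 kept reads in endosperm, 3662887 in embryo and 3927360 in seed coat. Except where the construction of a setting shows it, the cause was not tested.

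Scaling to miRNA reads moved each library by 1 factor. The medians of mother over father were −2.34 (nrpd1a) and −2.81 (rdr2), and 333 and 75 windows were lower with the mutant father. Dominant windows were 3208 in embryo, 105 in endosperm and 5 in seed coat, where medians of mother over father were 0.70 (nrpd1a) and 0.27 (rdr2) in embryo windows and −5.43 and −6.91 in endosperm windows. Listed genes higher were 0 in nrpd1a × nrpd1a and 0 in rdr2 × rdr2. With the nrpd1a mother 18 were lower and 1 higher, with the rdr2 mother 22 and 0, and in embryo against endosperm 7 and 1. Reads near AGL87 reversed to 0.737 in nrpd1a × nrpd1a and 0.824 in rdr2 × rdr2. With the rdr2 mother HDG3 reversed to 0.866, FIS2 to 0.862 and PKR2 to 0.934. In embryo over endosperm TAR1 reversed to 1.15, SDC to 1.43, AGL34 to 1.15 and AGL90 to 1.16. TAS reads were at 0.689 in nrpd1a × nrpd1a, 0.734 in rdr2 × rdr2, 1.71 and 0.891 in the nrpd1a and rdr2 reciprocal crosses, 10.1 in embryo over seed coat, 3.94 in endosperm over seed coat and 2.58 in embryo over endosperm.

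With the same scaling, miRNA families higher and lower were 9 and 5 in nrpd1a × nrpd1a, 10 and 4 in rdr2 × rdr2, and 7 and 2 with the rdr2 mother. With the nrpd1a mother 9 were higher, in embryo against seed coat 8 were lower, and in embryo against endosperm 10 were higher and 6 lower. Ratios that reversed in nrpd1a × nrpd1a were miR156 0.611, miR157 0.742, miR165 0.486, miR168 0.650, miR171 0.907, miR173 0.622, miR775 0.751 and miR822 0.807. In rdr2 × rdr2 they were miR156 0.615, miR168 0.685, miR171 0.781, miR173 0.790, miR395 0.989, miR775 0.944, miR822 0.887 and miR824 0.528. With the rdr2 mother they were miR158 0.858, miR167 0.908 and miR827 0.970, in embryo over seed coat miR165 1.04, miR168 1.04 and miR822 1.05, and in embryo over endosperm miR158 1.27, miR171 1.39 and miR173 1.07.

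Without the 45S block the medians of mother over father were −1.09 (nrpd1a) and −1.14 (rdr2), dominant windows 2597 in embryo and 64 in endosperm, and the endosperm medians −2.57 and −2.23. The 24-nt share ratios were 0.0432 and 0.0435 in nrpd1a × nrpd1a and rdr2 × rdr2, 0.271 and 0.210 in the nrpd1a and rdr2 reciprocal crosses, 1.15 for embryo and 1.08 for endosperm over seed coat, the embryo value reversed. Listed genes higher were 2 in nrpd1a × nrpd1a and 2 in rdr2 × rdr2, and 9 were lower with the rdr2 mother. In endosperm against seed coat 1 was lower and 8 higher, and in embryo against endosperm 7 and 1. In embryo over endosperm TAR1 reversed to 1.05, SDC to 1.32, AGL34 to 1.06, AGL90 to 1.07, miR158 to 1.16 and miR171 to 1.28. TAS reads were at 4.19 in nrpd1a × nrpd1a, 4.30 in rdr2 × rdr2, 4.10 and 2.84 in the reciprocal crosses, 5.47 and 2.31 in embryo and endosperm over seed coat and 2.36, reversed, in embryo over endosperm. There 10 miRNA families were higher and 6 lower. Embryo markers had 1383 RPM in embryo and seed coat markers 1047 in seed coat, as a smaller denominator gives. Scaled to unique 24-nt reads, 2794 windows were dominant in embryo and 64 in endosperm, and 966 were lower in nrpd1a × nrpd1a and 1041 in rdr2 × rdr2. At these the medians of mother over father were −3.23 (nrpd1a) and −3.71 (rdr2), the correlation 0.956, and 681 were lower with the nrpd1a mother and 99 with the father, 711 and 109 for rdr2. At the windows lower in RPM the medians reversed to 1.02 (nrpd1a) and 1.34 (rdr2), with 1449 lower with the nrpd1a mother and 3617 with the father, and 1346 and 3859 for rdr2.

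The settings of read and window choice kept the direction of the medians of mother over father. At 50 reads per window, which tests fewer windows, 3479 were lower in nrpd1a × nrpd1a and 3479 in rdr2 × rdr2. The medians were then −2.64 (nrpd1a) and −2.78 (rdr2), with 2714 lower with the nrpd1a mother and 194 with the father, and 2791 and 146 for rdr2. The correlation of the reciprocal ratios was 0.939, dominant windows 25, 221 and 10 in embryo, endosperm and seed coat, and the endosperm medians −2.91 and −3.38. Without sequences read once the medians were −2.84 (nrpd1a) and −2.97 (rdr2), with 451 and 379 windows lower with the mutant father and a correlation of 0.874. Dominant were then 214 windows in embryo and 12 in seed coat, with endosperm medians −3.27 and −3.93 and seed coat medians −4.79 and −5.66. Windows of 1000 bp gave medians −0.92 (nrpd1a) and −1.004 (rdr2), a correlation of 0.938, 34 embryo windows and endosperm medians −1.35 and −1.39. With matches shared the medians were −1.16 (nrpd1a) and −1.25 (rdr2), the correlation 0.943, the endosperm windows 916 and their medians −1.41 and −1.55, and PKR2 reversed to 0.435 with the nrpd1a mother and 0.309 with the rdr2 mother. With 23-nt reads added the medians were −1.33 (nrpd1a) and −1.38 (rdr2) and 44 windows were dominant in seed coat.

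The 24-nt share ratios for distinct sequences were 0.296 and 0.290 in nrpd1a × nrpd1a and rdr2 × rdr2, 0.976 and 1.00 in the nrpd1a and rdr2 reciprocal crosses, 1.31 for embryo and 1.25 for endosperm over seed coat, with the rdr2 and embryo values reversed. For reads with 1 match they were 0.0974 and 0.0926 in nrpd1a × nrpd1a and rdr2 × rdr2, 0.394 and 0.341 in the nrpd1a and rdr2 reciprocal crosses, 1.102 for embryo and 1.06 for endosperm, with embryo reversed. For all deposited reads they were 0.105 and 0.108 in nrpd1a × nrpd1a and rdr2 × rdr2, 0.289 and 0.240 in the nrpd1a and rdr2 reciprocal crosses, 0.785 for embryo and 1.73 for endosperm, and with structural and organelle reads kept 0.104 and 0.107 in nrpd1a × nrpd1a and rdr2 × rdr2, 0.288 and 0.238 in the nrpd1a and rdr2 reciprocal crosses, 0.781 for embryo and 1.72 for endosperm. Reads of 18 to 28 nt gave 0.881 for embryo and 1.60 for endosperm. Among reads with 1 match the pericentromeric percent was 28.4 in wild type × wild type, 18.9 and 16.8 in nrpd1a × nrpd1a and rdr2 × rdr2, 51.9 and 53.0 with the nrpd1a and rdr2 mothers and 28.9 and 29.3 with the fathers. It was 73.7 in embryo, 44.5 in endosperm and 31.2 in seed coat.

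With the gene body only, listed genes higher were 2 in nrpd1a × nrpd1a, 2 in rdr2 × rdr2, 2 and 1 with the nrpd1a and rdr2 mothers and 2 in embryo against seed coat, and 10 were lower in rdr2 × rdr2. LIG6 reversed to 4.47 in endosperm over seed coat and AT5G36210 to 0.339 in embryo over endosperm. With 2 kb, 2 were higher in rdr2 × rdr2. TAS reads of 20 to 22 nt gave 3.14 in the nrpd1a reciprocal cross. With all annotated mature sequences, each counted alone, 48 were higher and 2 lower in nrpd1a × nrpd1a, 47 and 2 in rdr2 × rdr2, 46 and 1 with the nrpd1a mother and 49 and 1 with the rdr2 mother. In endosperm against seed coat 20 were higher, and in embryo against endosperm 23 lower. Marker reads of 25 to 30 nt were 222 RPM for embryo, 6.04 for endosperm and 239 for seed coat, each in its own tissue.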

Other observations

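All comparisons in this part were chosen only after the data had been seen.

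Single sequences made up much of the rises near genes in the reciprocal crosses. Of the 10 genes with the largest rise with a mutant mother, 6 had over 50% of their 24-nt reads in 1 sequence for nrpd1a and 6 for rdr2, and 8 genes were on both lists. AT1G78480 and AT1G78476 are each counted in these numbers, though their leading sequence is the same. At AT2G23834 the sequence AGATCCATGTAGACGCGCTAGGTT (chromosome 2, 10149133 to 10149156, minus strand, in an exon) held 52.0% of the reads with the nrpd1a mother, with 6444 reads in nrpd1a × wild type and 4819 in rdr2 × wild type. It had 16 in wild type × nrpd1a, 31 in wild type × rdr2, 26 in wild type × wild type, 575 in nrpd1a × nrpd1a and 650 in rdr2 × rdr2, and 0 in each of the 3 tissues. In an intron of AT1G78476, AACGGAGGAGTTTGTTTGTTGTAC (chromosome 1, 29525192 to 29525215, plus strand) held 83.9%, with 4214 and 3832 reads with the mutant mothers against 30 and 32 with the mutant fathers. In the flank of cICDH, TCAACCTTTGGTTTCTCGGATGAT (chromosome 1, 24543693 to 24543716, minus strand) held 97.1%, with 618 and 676 RPM with the nrpd1a and rdr2 mothers against 27.5 and 30.2 with the fathers and 38.9 in wild type × wild type. These sequences were also present in the homozygous mutants, at 202 and 210 RPM for the last.

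The loss at siRNA loci extended to other read lengths. Over the 7704 windows lower in nrpd1a × nrpd1a, which were chosen on their 24-nt reads, 21-nt reads were 206-fold lower, 22-nt reads 323-fold, 23-nt reads 664-fold and 24-nt reads 375-fold, and in rdr2 × rdr2 234-fold, 411-fold, 873-fold and 643-fold. Between the reciprocal crosses 21-nt reads differed most of these lengths, 44.2-fold for nrpd1a and 55.3-fold for rdr2, against 14.2-fold and 20.0-fold at 24 nt. A first base A, the base preferred by AGO4, was found in 67.1% of uniquely matched 24-nt reads in nrpd1a × wild type, 66.8% in wild type × nrpd1a, 68.5% in embryo, 59.96% in endosperm, 51.9% in seed coat, 54.1% in wild type × wild type and 48.1% in nrpd1a × nrpd1a. Uniquely matched reads were 27.1% of 24-nt reads in nrpd1a × nrpd1a, 54.9% in nrpd1a × wild type and 87.2% in wild type × wild type. The percentages thus describe unlike parts of the libraries.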
